A study of Homo sapiens with 6 samples.

How the data were processed

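Gene expression was measured by RNA sequencing in Huh-7 cells, a human hepatoma line that keeps many functions of the hepatocyte. Per the labels' protocols, the cells were loaded with oleic acid (100 µM, 24 h) as a high-lipid model, starved, and then given either vehicle (DMSO, 0 µM pectolinarigenin) or pectolinarigenin, a plant flavone, at 100 µM for 24 h. Total RNA was extracted with TRIzol and made into libraries with a VAHTS Universal V8 kit, per the labels' protocols. Each group had 3 libraries, numbered 1 to 3 in the labels. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

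The deposited table listed 60605 Ensembl gene identifiers, of which 40591 had a symbol, with a raw count and an FPKM value for each of the 6 libraries. The authors' counts were whole numbers that had not been normalized. The authors' FPKM values were tested against the counts: over 2422 genes above 20 FPKM in at least 2 libraries, each count divided by the library's total and its FPKM gave 1 length per gene, with a largest coefficient of variation of 0.00032 across libraries. The deposited FPKM were therefore scaled by the sum of all listed counts and by a gene length. Of those lengths, 68.3% lay within 2% of the summed exon length in GENCODE 29. Whether the rest differ in annotation or in how the length was defined cannot be told from these values. The tools named were cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 with the genome build GRCh38, per the submitters' processing notes. Which tool did which step, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here.

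The comparison was designed before the data were examined, with limma on log2(FPKM + 1) as the test for FPKM values and edgeR as the test if counts were present. Counts were present, so the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was used, with TMM scaling factors, no covariate and 2-sided p-values. Genes were tested if their mean FPKM over the 6 libraries was at least 1, which left 12829 genes, and adjusted p-values are Benjamini-Hochberg values over these genes with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. The biological coefficient of variation was 0.0614. The 34 gene lists were also fixed before the data were examined. Some genes are in more than 1 list, for example SLC7A5, SLC7A11, GDF15, ATF3, JUNB and FGA, so the lists are not independent. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives.

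The genes named were set by a rule written before the data were examined. It took the 10 largest rises and the 10 largest falls among symbol-bearing genes that passed the test with no overlap between groups. It also took up to 3 members with the smallest p in the direction of each called list, the member with the smallest p of every other list, and 12 fixed genes of lipid and liver metabolism, among them SREBF1, FASN, SCD, PPARA, CPT1A, PLIN2, APOB, CYP7A1, CYP1A1 and ALB. Some genes that the rule names, and a called gene family, are not reported here. Any other gene named was chosen after its values were seen. Gene positions and types were taken from GENCODE 29 on GRCh38 by Ensembl identifier. Where all control counts of a gene were 0, its fold is a lower bound computed against 3 counts summed over the group. Ratios of genes with 1 to 3 counts in a group carry a 95% interval, and these bounds and intervals cover counting error only.

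Total counts per library ranged from 15140022 to 20311261, so that 3 counts in a library correspond to 0.148 to 0.198 CPM (counts scaled to a common library total). No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom was 1.53 to 2.73 within the control group and 4.51 to 11.1 within the treated group. The pipeline was tested on simulated counts drawn for the 12829 genes of this comparison, with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 82 and 86 of them, and 13 unchanged genes were called (7.18% of all calls, above the nominal 5%). Of 31 unchanged lists 0 were called and the list planted as higher was called. The simulated genes were drawn independently of each other, so this does not test camera where genes of a list are correlated. In the data 6486 genes were called, with a median absolute log2 fold change of 0.40. The simulation changed far fewer genes, by larger folds, so its recovery and false-call share do not carry over to the data.

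The alternatives in limma 3.58.1 were other pseudocounts, scalings and variance trends for FPKM. Those in edgeR were other expression filters, median-of-ratios scaling (6487 changed genes), a replicate block and each library left out in turn. Also tried were a threshold of 0.01, DESeq2 1.42.0, library size without TMM factors, offsets for GC content and gene length, and protein-coding genes alone. The last 4 and limma on log2(FPKM + 1) as a test in its own right were added after the data were seen. Figures were drawn with matplotlib 3.10.9.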

Results

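The study asked how pectolinarigenin changes gene expression in Huh-7 hepatoma cells that had been loaded with oleic acid. RNA was sequenced from 3 control libraries (vehicle) and 3 libraries of cells given 100 µM pectolinarigenin for 24 h. Total counts were 18619775, 18652800 and 15140022 in control libraries 1 to 3 and 16054283, 16297404 and 20311261 in treated libraries 1 to 3. The gene with the most counts in every control library was ALB, which encodes albumin, with 1.86% to 1.89% of all counts. In every treated library it was MT-CO1, a mitochondrially encoded subunit of cytochrome c oxidase, with 1.30% to 1.41%. These counts were not divided by gene length, so they do not rank the transcripts by abundance.

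Libraries of the same group resembled each other more than libraries of different groups. Pearson's r of log2(FPKM + 1) across the tested genes, which are not independent replicates, was 0.991 to 0.992 between control libraries, 0.987 to 0.990 between treated libraries and 0.958 to 0.965 between the groups. The first principal component held 70.5% of the variance and separated the groups. The second held 10.2% and set treated library 3 apart from treated libraries 1 and 2. Treated library 3 also had the highest total count.

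**Figure D1:**
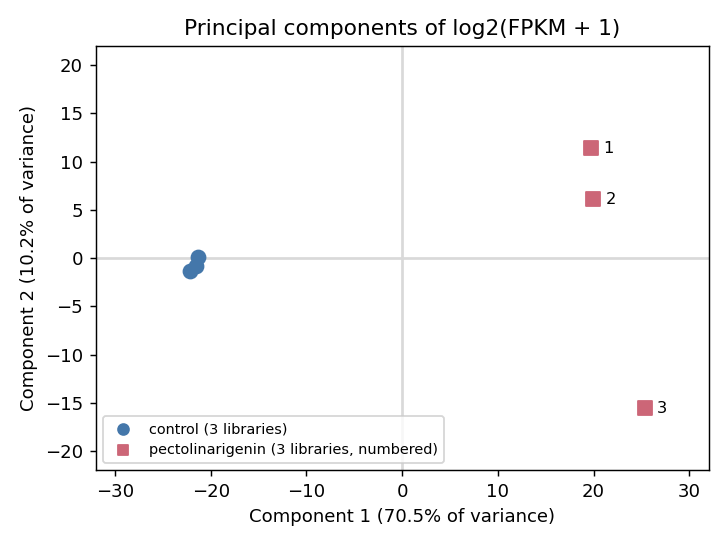
First and second principal components of log2(FPKM + 1) over the tested genes, with 1 point per library (circles, control; squares, pectolinarigenin, numbered by replicate). The axes carry 70.5% and 10.2% of the variance, the groups separate on the first, and treated library 3 lies apart from the other treated libraries on the second.

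The largest rises were in metallothioneins, small metal-binding proteins, whose transcripts were low in control cells (at most 2.77 FPKM on average for the 8 with the largest rises). CYP1A1, a detoxifying enzyme induced through the aryl hydrocarbon receptor, rose 17.9-fold, and 20 of 22 tested immediate early genes rose. Most tested genes of ATF4 and amino acid stress and of inflammatory signalling rose too, but these lists had adjusted p = 0.0852 and 0.0548 with an estimated correlation. Of the tested genes, 15 of 25 in cholesterol synthesis and uptake, 15 of 23 in fatty acid and triglyceride synthesis, 22 of 32 in DNA replication and 19 of 27 hepatocyte genes fell, mostly by less than 2-fold. In that order, these lists had adjusted p = 0.447, 0.360, 0.166 and 0.209 with an estimated correlation. Of 12829 tested genes, 6486 changed at an adjusted p under 0.05 (edgeR), 3243 higher and 3243 lower. This balance follows from the TMM scaling, which centres the fold changes: 56.9% of the changed genes were higher without TMM factors, and 57.5% in limma on log2(FPKM + 1). Of these, 497 changed at least 2-fold, 251 higher and 246 lower. The changes were mostly small: the median absolute log2 fold change of the changed genes was 0.40, and 1378 of them had an absolute log2 fold change under 0.26. In 7557 tested genes (58.9%) the 3 treated values lay entirely above or below the 3 control values, where chance gives 10%. The 2-fold count depends on how low expression is handled, since 1488 genes passed it without an expression filter and 153 at a mean FPKM of at least 5. Without single libraries it was 443 to 534.

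Among the 10 largest rises were 8 metallothioneins of the cluster on chromosome 16. MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497, GRCh38) rose from 2.77 ± 0.35 to 269.7 ± 48.8 FPKM (SD, n = 3 each), a log2 fold change of 6.56 with an SE of 0.15. MT1E (7.46, SE 0.23), MT1X (6.67, SE 0.32) and MT1F (6.10, SE 0.19) rose 176-fold, 102-fold and 68.8-fold. MT1G had 0 counts in all control libraries and 147 to 299 in the treated ones, which makes it at least 195-fold higher. MT1B, also at 0 in every control library, was at least 22.6-fold higher. MT1M had 2 control counts against 346 treated counts, a ratio of 168 (95% interval 46.1 to 1391), and the pseudogene MT1L had 1 against 226, a ratio of 219 (95% interval 38.9 to 8697). These genes are near-identical copies, so the division of reads among them is uncertain. The other rises among the 10 were RNU7-26P and RNA5SP474, a pair of small-RNA pseudogenes that rest on only 13 and 10 counts over the treated libraries and 0 over the controls. In the list of metallothioneins and zinc transport, 8 of 11 tested members rose, SLC39A10 fell and 2 did not pass (adjusted over the list alone, 9 rose and 1 fell). The list's median log2 fold change was 6.10, also with MT1G at its bound. Chosen after their values were seen, as were all genes outside the naming rule, the zinc exporter SLC30A1 rose by 1.44 (SE 0.12) and the zinc importer SLC39A10 fell by 2.05 (SE 0.13) on the log2 scale. The list was called higher (camera, adjusted p = 1.06e-26; adjusted p = 0.0485 with an estimated correlation).

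Among the 10 largest falls, UGT2B10, which conjugates lipophilic compounds with glucuronic acid, fell from 2.03 ± 0.18 to 0.233 ± 0.047 FPKM (SD, n = 3 each; log2 fold change -3.14, SE 0.22). The transcription factor TFEC changed by -2.87 (SE 0.20) and GABRB1, a subunit of the GABA-A receptor, by -2.86 (SE 0.24). PKLR (ENSG00000143627, chromosome 1, 155289293 to 155301438), the liver pyruvate kinase, fell from 6.70 ± 0.51 to 1.06 ± 0.13 FPKM (SD, n = 3 each; log2 fold change -2.70, SE 0.12). TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), a thioredoxin-binding protein that restrains glucose uptake, fell from 107.1 ± 2.1 to 19.1 ± 4.0 FPKM (SD, n = 3 each; log2 fold change -2.53, SE 0.11). UGT2B10 and the mitochondrial pseudogene MTND4P20 (-2.53, SE 0.45) share sequence with close copies, so their counts are uncertain. A further 3 rest on few counts: MIR559 had 11 counts over the control libraries and 0 over the treated ones, MIR5581 had 10 against 1, a ratio of 0.0970 (95% interval 0.0022 to 0.682), and RNU6-583P had 13 against 2, a ratio of 0.149 (95% interval 0.0163 to 0.659). MIR5581 and RNU6-583P each passed in 13 of 19 alternatives (adjusted p from 0.00311 to 0.104 and from 0.00796 to 0.141). MIR5581 lost its call without control library 1 (0.0860) or 3 (0.104) or treated library 1 (0.0894) or 2 (0.103), and its log2 fold change was -4.77 without treated library 3. RNU6-583P lost it without control library 1 (0.141) or 2 (0.0586) or treated library 2 (0.102) or 3 (0.0569). Both also lost it without the expression filter (0.0898 and 0.0744) and with a replicate block (0.0532 and 0.0600).

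**Figure D2:**
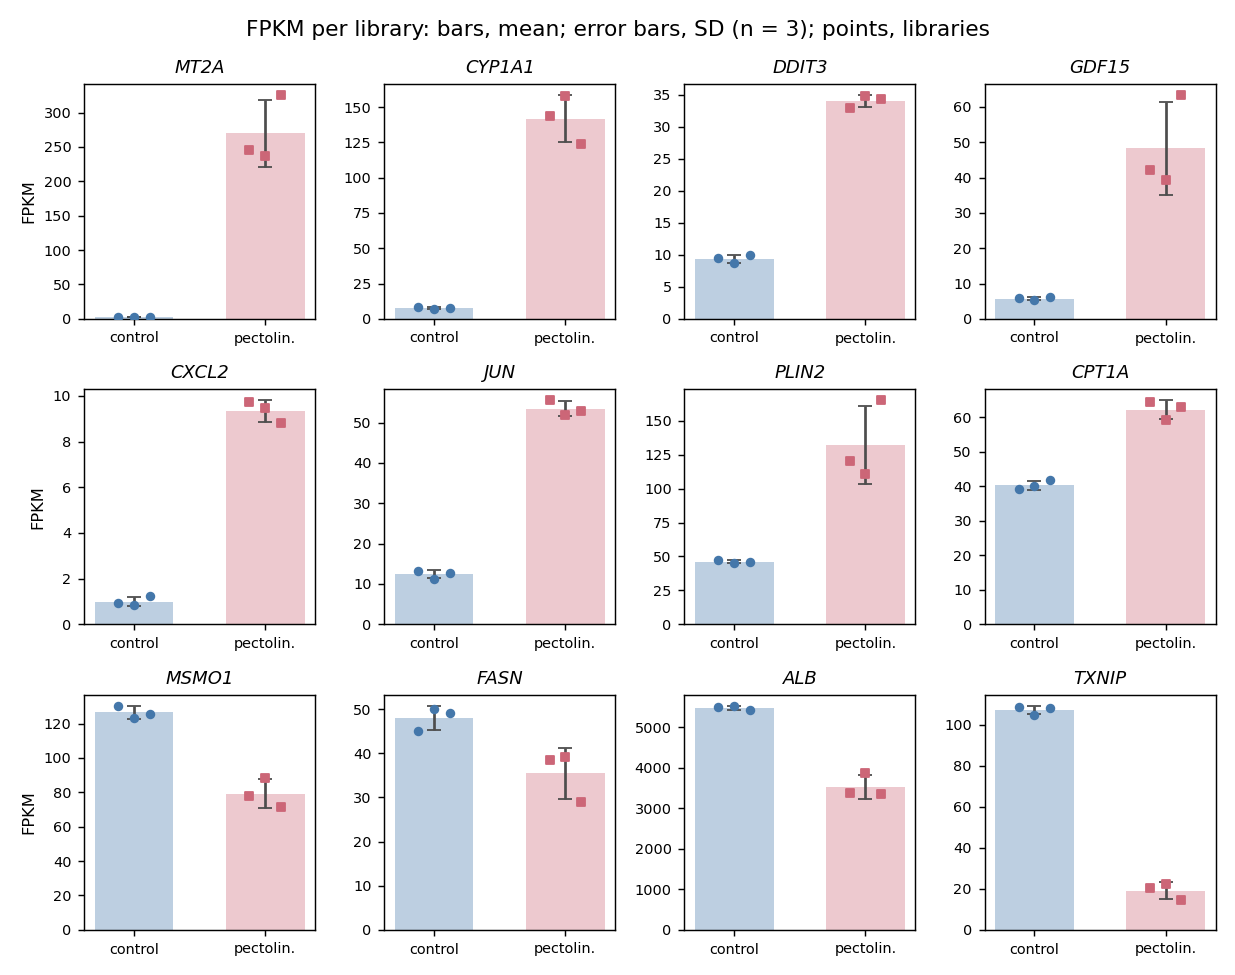
FPKM of 12 named genes in control and pectolinarigenin-treated (pectolin.) libraries, with bars for the mean, error bars for the SD (n = 3) and points for single libraries, on linear axes that start at 0. In each of the 12 genes the treated libraries lie entirely on one side of the control libraries, from MT2A (2.77 to 269.7 FPKM) to TXNIP (107.1 to 19.1 FPKM).

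Stress-response lists differed in how many of their genes rose. Of 12 listed targets of the aryl hydrocarbon receptor 5 passed the expression filter, and these rose: CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) from 7.69 ± 0.54 to 141.9 ± 16.8 FPKM (SD, n = 3 each; log2 fold change 4.16, SE 0.089), the amino acid transporter SLC7A5 by 1.41 (SE 0.10) and TIPARP by 0.81 (SE 0.060), with NFE2L2 at 0.42 and NQO1 at 0.20. The other 7 were not tested, and their counts went both ways. UGT1A1 had 95, 110 and 77 counts in the control libraries and 32, 43 and 40 in the treated ones, UGT1A6 had 31, 20 and 28 against 15, 8 and 9, and AHRR had 8, 5 and 7 against 3, 4 and 3. CYP1A2 had 27, 25 and 16 against 66, 75 and 44. The counts of CYP1B1 (68 to 95 against 73 to 81) and ALDH3A1 (22 to 31 against 22 to 27) overlapped, and LRAT had 1 count in all. Of 22 tested genes of ATF4 and amino acid stress, 20 rose, 0 fell and 2 did not pass (PSPH at 0.014, SE 0.059, and PCK2 at -0.13, SE 0.068). Among those that rose were the transcription factors ATF3 (2.85, SE 0.15) and DDIT3 (1.83, SE 0.081) and the amino acid transporter subunit SLC3A2 (1.87, SE 0.064). Of 17 tested heat shock genes 14 rose and 1 fell (HSPB1 at -0.26, SE 0.059), led by the chaperones HSPA8 (1.15, SE 0.055), HSPH1 (1.12, SE 0.060) and DNAJA1 (0.96, SE 0.069). Of 29 tested genes of autophagy and lysosomes 16 rose and 4 fell, with the sialidase NEU1 (1.29, SE 0.057), the cargo receptor SQSTM1 (1.15, SE 0.071) and MAP1LC3B (0.69, SE 0.060) at the smallest p. The endoplasmic reticulum chaperones were divided, with 8 of 21 higher, 4 lower (PDIA4, PDIA6, CALR and XBP1) and a median of 0.0079. HERPUD1 (1.03, SE 0.062), DNAJB11 (0.72, SE 0.053) and DNAJB9 (0.69, SE 0.064) rose. Counted with p-values adjusted over the list alone, the numbers that rose and fell were 5 and 0, 20 and 0, 14 and 1, 17 and 4, and 8 and 5 for these 5 lists. Camera called all 5 higher, with adjusted p = 1.29e-14, 1.99e-25, 2.03e-07, 0.000201 and 0.0321 in the same order. In that order, the lists had adjusted p = 0.0169, 0.0852, 0.120, 0.0754 and 0.606 with an estimated correlation. Of these 5 the aryl hydrocarbon receptor list kept its call. It rests on 5 tested genes, of which SLC7A5 is also in the ATF4 list. The correlation was estimated at -0.019 for this list and at 0.45 for the ATF4 list, so kept and lost calls do not rank the lists. The endoplasmic reticulum list was called in 10 of 23 alternatives (adjusted p from 0.000554 to 0.606), and without treated library 3 its adjusted p was 0.0712.

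Of 16 tested NF-kB and inflammatory genes 14 rose and 1 fell (TNFAIP2 at -0.54, SE 0.10; the same numbers adjusted over the list alone), including the chemokine CXCL2 (from 0.997 ± 0.206 to 9.33 ± 0.47 FPKM, SD, n = 3 each; log2 fold change 3.20, SE 0.16) and the feedback inhibitors TNFAIP3 (2.05, SE 0.089) and NFKBIA (1.76, SE 0.083). Of 22 tested immediate early genes 20 rose and 0 fell (20 and 0 adjusted over the list alone), with DUSP1 at 2.25 (SE 0.078), JUN at 2.07 (SE 0.066) and JUNB at 1.89 (SE 0.079). Both lists were called higher (camera, adjusted p = 2.2e-15 and 1.06e-26). The inflammatory list had adjusted p = 0.0548 with an estimated correlation and the immediate early list 0.0169. Replication-dependent histone transcripts, whose RNA normally ends without a poly(A) tail, rose in 9 of 10 tested genes, with H2BC4 at 0.26 (SE 0.26; 9 rose and 0 fell adjusted over the list alone). H2BC21 (3.12, SE 0.15), H2BC5 (2.87, SE 0.12) and H2AC6 (2.09, SE 0.078) had the smallest p-values. Whether the reads of these genes came from RNA with or without a poly(A) tail was not tested. The histone list was called higher (adjusted p = 3.22e-19; 0.0169 with an estimated correlation), although near-identical histone copies make the values of single genes uncertain.

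Of 25 tested genes of cholesterol synthesis and uptake 15 fell and PMVK rose (16 and 1 adjusted over the list alone). MSMO1, a sterol methyl oxidase, fell from 126.4 ± 3.5 to 79.2 ± 8.6 FPKM (SD, n = 3 each; log2 fold change -0.71, SE 0.068), and HMGCS1 changed by -0.59 (SE 0.072). Of 23 tested genes of fatty acid and triglyceride synthesis 15 fell and 2 rose, ACSL1 and AGPAT2 (16 and 2 adjusted over the list alone). Examples are GPAM (-0.64, SE 0.086), ACSL4 (-0.56, SE 0.052), ELOVL6 (-0.49, SE 0.058), FASN, the fatty acid synthase (-0.48, SE 0.088), and SCD (-0.27, SE 0.061). SREBF1, which encodes a transcription factor that drives lipid synthesis, had a log2 fold change of -0.089 (SE 0.073) and did not pass (adjusted p = 0.329). Without single libraries it ranged from -0.16 to -0.036. Both lists were called lower (camera, adjusted p = 0.000492 and 0.00245), with adjusted p = 0.447 and 0.360 with an estimated correlation.

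Other lipid genes moved in both directions. PLIN2 (ENSG00000147872, chromosome 9, 19108375 to 19149290), which coats lipid droplets, rose from 46.3 ± 1.2 to 132.1 ± 28.9 FPKM (SD, n = 3 each; log2 fold change 1.48, SE 0.11), while 2 of 11 tested genes of lipid droplets and lipolysis rose (PLIN2 and PLIN4) and 2 fell (PLIN3 and LIPA). CPT1A, which admits fatty acids to mitochondria, rose by 0.59 (SE 0.057) and the peroxisomal thiolase ACAA1 by 0.89 (SE 0.068). In the list of fatty acid oxidation and ketone formation 7 of 21 rose and 6 fell, its median was -0.020, its mean 0.10 and its test pointed up. PPARA, a transcription factor of fatty acid oxidation, had a log2 fold change of -0.020 (SE 0.10; adjusted p = 0.881), with -0.15 without treated library 1 (adjusted p = 0.141) and 0.12 without treated library 3 (0.0829). Among 21 tested genes of lipoproteins and lipid transport 7 rose and 6 fell, with a median of 0.0014, a mean of 0.021 and a test that pointed down. APOH fell by 1.16 (SE 0.080) on the log2 scale, while APOA4 rose by 2.16 (SE 0.20) and APOA2 by 1.08 (SE 0.080), the last 2 chosen after their values were seen. APOB, a structural protein of lipoproteins, had a log2 fold change of -0.24 (SE 0.094; adjusted p = 0.0432), with overlapping groups, and passed in 5 of 22 alternatives (adjusted p from 8.49e-05 to 0.332). Without control libraries 1, 2 and 3 in turn its adjusted p was 0.151, 0.104 and 0.0879, and without treated library 2 it was 0.107. Its log2 fold change was -0.13 without treated library 3 (adjusted p = 0.0795) and -0.39 without treated library 1 (0.00011). In the bile acid list 3 of 12 rose and 5 fell, with the transporter ABCC3 higher by 0.71 (SE 0.055). CYP7A1, the rate-limiting enzyme of bile acid synthesis, had 0 counts in all 6 libraries, which allows up to 0.148 to 0.198 CPM per library, for counting error alone. Camera called none of these 4 lists (edgeR counts; adjusted p = 0.589, 0.445, 0.637 and 0.445 for droplets, oxidation, lipoproteins and bile acids). Their unadjusted p-values were 0.532, 0.354, 0.617 and 0.339, and fry called only the bile acid list (adjusted p = 0.0206). Adjusted over the list alone, 2 rose and 2 fell among the droplet genes, 7 and 6 in oxidation, 7 and 6 among lipoproteins and 3 and 6 in the bile acid list.

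Of 27 tested hepatocyte genes 19 fell and 2 rose (C3 and FOXA3), the same numbers as adjusted over the list alone. ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412) fell from 5475 ± 52 to 3530 ± 293 FPKM (SD, n = 3 each; log2 fold change -0.67, SE 0.066), the fibrinogen chains FGA and FGB changed by -1.08 (SE 0.069) and -0.63 (SE 0.059), and AHSG by -0.90 (SE 0.065). Of 19 tested acute phase and STAT3 targets 11 fell and 3 rose, JUNB, MYC and PIM1 (12 and 4 adjusted over the list alone). Among those that fell were haptoglobin, HP (-1.91, SE 0.070), and LBP, which binds bacterial lipopolysaccharide (-2.06, SE 0.11). FGA and FGB are in both the hepatocyte list and the acute phase list. Of 15 tested xenobiotic and PXR genes 7 fell and 2 rose, POR and ALAS1 (7 and 2 adjusted over the list alone). Falling genes included the glutathione transferases GSTA2 (-1.73, SE 0.11) and GSTA1 (-1.08, SE 0.10) and the glucuronosyltransferase UGT2B4 (-1.10, SE 0.084), whose close copies can share reads. The 3 lists were called lower (camera, adjusted p = 2.03e-07, 0.000454 and 0.00323). In that order, the lists had adjusted p = 0.209, 0.0754 and 0.121 with an estimated correlation.

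Of 32 tested genes of DNA replication and G1/S 22 fell and RFC3 rose (23 and 2 adjusted over the list alone), with the replicative helicase subunit MCM4 at -0.78 (SE 0.054), the ribonucleotide reductase subunit RRM2 at -0.76 (SE 0.066) and UHRF1 at -0.75 (SE 0.065). Of 33 tested genes of mitosis and G2/M 14 fell and 9 rose (16 and 9 adjusted over the list alone), and the median was -0.011. TOP2A, which untangles DNA, fell from 197.8 ± 5.1 to 107.6 ± 4.7 FPKM (SD, n = 3 each; log2 fold change -0.92, SE 0.055), and CDK1 changed by -0.79 (SE 0.062) and UBE2C by -0.62 (SE 0.056). In glycolysis 8 of 21 tested genes fell and 4 rose, the glucose transporter SLC2A1, HK2, ENO2 and PFKFB3 (11 and 4 adjusted over the list alone). Among those that fell, PKLR, the transporter SLC2A2 (-1.61, SE 0.13) and ALDOC (-0.93, SE 0.15) had the smallest p. Camera called these 3 lists lower (adjusted p = 2.18e-06, 0.0212 and 0.0321). In that order, the lists had adjusted p = 0.166, 0.194 and 0.676 with an estimated correlation. The glycolysis list was called in 10 of 23 alternatives (adjusted p from 6.24e-05 to 0.676) and not without treated library 1 (0.114) or treated library 2 (0.259). The mitosis list was called in 14 of 23 (adjusted p from 0.000872 to 0.194).

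The remaining 10 lists were not called by camera on the edgeR counts, although single members changed. Of all the lists that were not called, 1 had an unadjusted p under 0.05, the p53 targets (0.0304). Fry called p53 targets, apoptosis regulators and matrix genes higher (adjusted p = 0.00617, 0.0188 and 0.0301). Of 20 tested p53 targets 10 rose and 4 fell (adjusted p = 0.0524 for the list, 0.000122 to 0.447 over the alternatives; 0.0104 without treated library 3, 0.0297 without treated library 1 and 0.0421 without control library 3), with the stress cytokine GDF15 at 3.05 (SE 0.16). Among NRF2 antioxidant targets 6 of 23 rose and 4 fell, with the cystine transporter SLC7A11 at 1.40 (SE 0.075). Both GDF15 and SLC7A11 are also in the list of ATF4 and amino acid stress. In the hypoxia list 5 of 18 rose and 3 fell, with P4HA1 at -1.09 (SE 0.090). Of 19 genes of gluconeogenesis and insulin signalling 5 rose and 6 fell, with IRS2 at 1.10 (SE 0.10). Interferon-stimulated genes numbered 3 higher and 5 lower of 11, with OAS1 at 1.30 (SE 0.13). Apoptosis regulators numbered 9 higher and 6 lower of 23, with BIRC3 at 1.12 (SE 0.13). Genes of extracellular matrix and TGF-beta numbered 9 higher and 5 lower of 16, with CCN1 at 1.77 (SE 0.16). Cytosolic ribosomal proteins changed little, with 9 of 35 higher, 0 lower and RPL14 at 0.25 (SE 0.057). This list was called higher in 10 of 23 alternatives (adjusted p from 0.00519 to 0.847), including without treated library 1 (0.00616). For the 15 mitochondrially encoded genes, 1 rose (MT-ND4) and 5 fell, with MT-ND5 at -0.45 (SE 0.058). The mitochondrial list was called lower without treated library 3 (adjusted p = 0.0108) and in 0 of the other 21 alternatives (up to 0.860). In the nuclear-encoded respiratory chain 2 of 31 rose (SDHB and COX5A) and 7 fell, with SDHC at -0.38 (SE 0.054). Adjusted over the list alone, the numbers that rose and fell were 11 and 4 for p53, 6 and 4 for NRF2, 5 and 3 for hypoxia, 6 and 6 for gluconeogenesis, 3 and 5 for interferon, 9 and 6 for apoptosis, 9 and 5 for matrix, 7 and 0 for ribosomal proteins, 1 and 2 for the mitochondrially encoded genes and 2 and 7 for the respiratory chain.

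Markers of other cell types were few and did not move one way. The fibroblast and stellate list had 2 tested members, RGS5 higher by 0.67 (SE 0.12) and PDGFRA at -0.53 (SE 0.11). The blood and immune list also had 2, with LYZ higher by 0.67 (SE 0.10) and CD14 at -0.63 (SE 0.17). The endothelial and cholangiocyte list had 4, of which KRT19 rose by 0.68 (SE 0.23), PECAM1 fell (-1.05, SE 0.10), and SOX9 at 0.017 (SE 0.056) and EPCAM at 0.11 (SE 0.060) did not pass. The numbers adjusted over the list alone were the same in these 3 lists, which were too short for a set test.

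**Figure D3:**
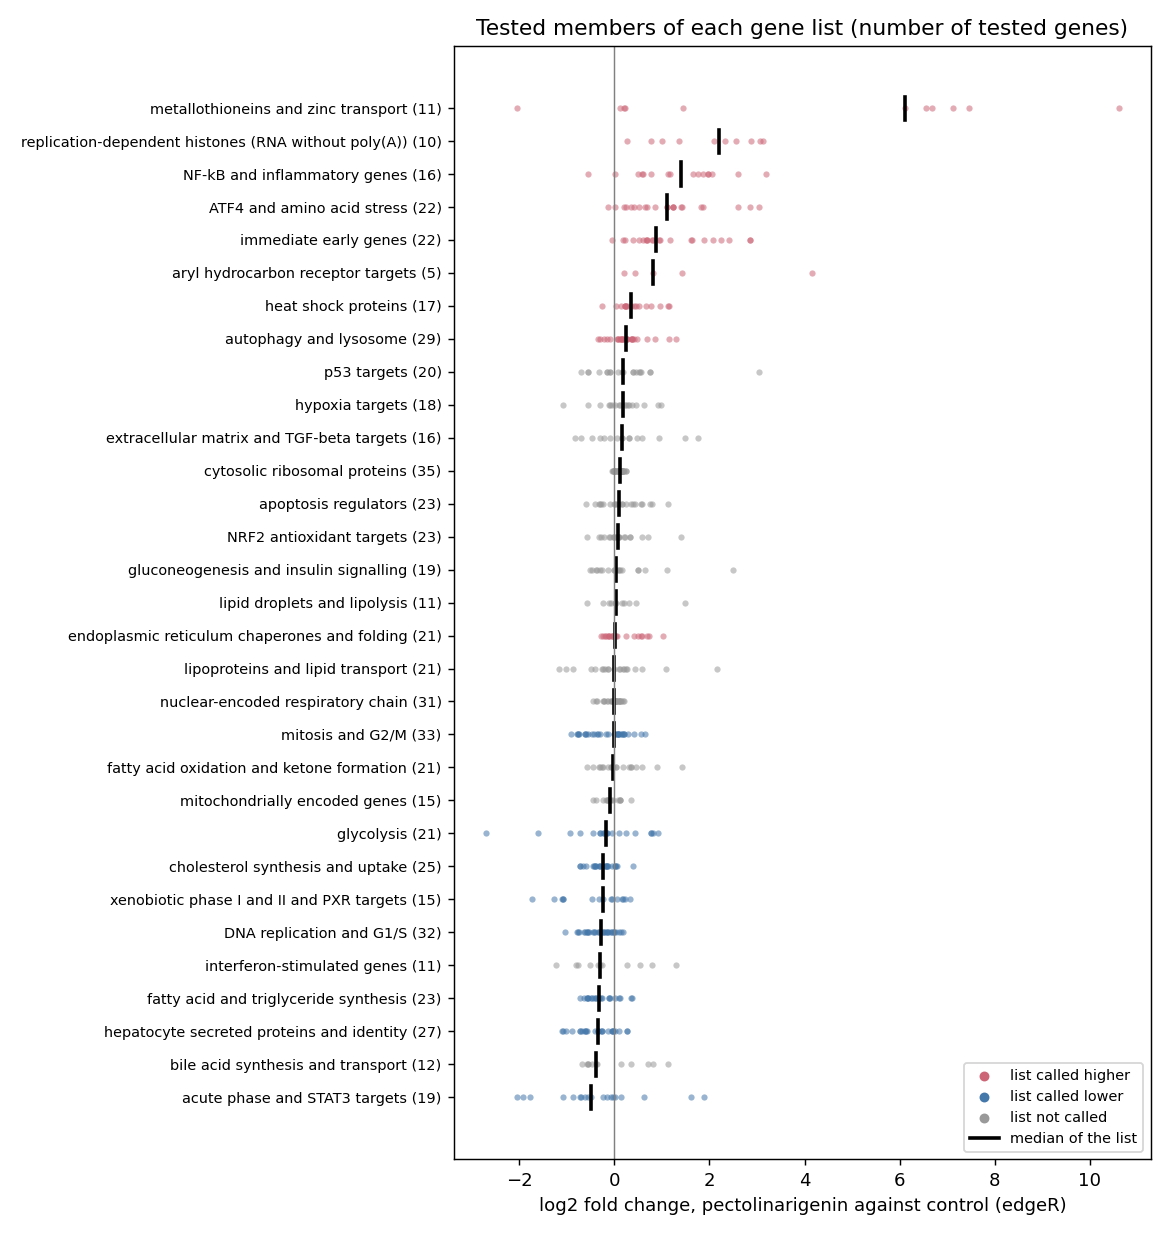
Log2 fold change (edgeR, pectolinarigenin against control) of each tested member of the 31 lists with a set test, with 1 point per gene, a black bar at the list's median and colour for camera's call at the preset correlation. The metallothionein list has the highest median (6.10), where the point near 10.6 is the fitted value of MT1G, whose control counts are all 0, and the histone list has the next highest (2.21).

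In all, 9 lists were called higher and 8 lower at camera's preset correlation. Under an estimated correlation 4 were called higher (aryl hydrocarbon receptor targets, immediate early genes, histones and metallothioneins) and 0 lower. At an unadjusted p under 0.05 those numbers were 8 and 2. The correlations were estimated from 6 libraries and differed between lists, so a kept or lost call does not rank the lists. With fry 12 were called higher and 8 lower. Fry tests whether a list's genes move one way on balance and does not compare them with other genes.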

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

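The alternatives of limma on log2(FPKM + 1), DESeq2, library size without TMM factors, GC and length offsets and protein-coding genes alone were chosen after the data were seen. No named gene or list that was called changed direction under the alternatives that were run, although with GC and length offsets 1 of the 6105 changed genes shared with the main analysis did. The settings on FPKM values were run in limma, so they change the test as well as the setting. Of 1988 comparisons of a named gene with its value in an alternative, 1959 stayed on the same side of the threshold. The other 29 no longer passed, all of them for APOB, MIR5581 or RNU6-583P. Of 711 comparisons of a list, 643 stayed on the same side, 47 no longer passed and 21 newly passed. Over genes and lists together, 15 values called in neither analysis differed in sign, and these are counted as staying on the same side. The count of 6486 changed genes became 4099 at a mean FPKM of at least 5 (2050 higher, 2049 lower), where only 7144 genes were tested. The count of 497 genes at 2-fold or more became 326 (pseudocount 0.5), 1488 (no filter), 153 (mean FPKM of at least 5), 220 (quantile normalization), 222 (no trend), 219 (robust trend), 226 (limma on log2(FPKM + 1)) and 319 (protein-coding genes). A pseudocount pulls the folds of low genes toward 0 by construction, and the filters change which genes are tested. For the other changes the cause was not tested. The 9 lists called higher became 4 and the 8 called lower became 0 with an estimated correlation, and 5 were called lower with quantile normalization and with TPM without the mitochondrially encoded and most abundant genes. The gap between the lowest Pearson's r within groups and the highest between groups was 0.0218, and it became 0.0303 (pseudocount 0.1), 0.0244 (pseudocount 0.5), 0.0085 (no filter) and 0.0340 (mean FPKM of at least 5). Leaving out each library in turn gave 5292 to 6516 changed genes, 443 to 534 at 2-fold or more, 9 to 11 lists higher and 7 to 9 lower. Without treated library 3, which stood apart on the second component, 6404 genes changed, 5903 of them among the 6486. DESeq2 called 5791 genes, with 498 adjusted p-values not given. The share of higher genes among those changed was 47.3% to 57.6% over the alternatives. The replicate numbers showed no pairing of the libraries. Correlations of deviations from the group means were -0.0069, 0.0246 and -0.0124 for the same number and -0.038 to 0.043 for different numbers. This does not exclude shared cultures or days. The fit with a replicate block called 6540 genes, with p53 targets newly called higher (camera, adjusted p = 0.0167). Depth limits the genes with few counts, for which folds are bounds or wide intervals.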

Other observations

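All tests in this part were chosen after the results were seen, except the comparisons with other splits of the libraries, which were set before those splits were run. Grouping genes by the leading letters of their symbols gave 197 families of at least 8 tested genes, of which camera at its preset correlation called 8 higher and 4 lower. The families are shared prefixes, not sets of 1 function, and some include pseudogenes or antisense RNAs. In the UTP family 9 of 10 tested genes rose and 0 fell (adjusted p = 0.00308, or 0.988 with an estimated correlation), and UTP14A rose from 4.31 to 8.80 FPKM (log2 fold change 0.99, SE 0.087). In the NOP family 7 of 9 rose and 0 fell (adjusted p = 0.0165, or 0.988 with an estimated correlation), with NOP58 at 0.76 (SE 0.072). Among SNHG genes, long RNAs that host small nucleolar RNAs, 9 of 18 rose and 0 fell (adjusted p = 0.0165, or 0.988 with an estimated correlation), with SNHG7 at 0.82 (SE 0.065). The DDX family of helicases had 19 of 32 higher and 5 lower (adjusted p = 0.0229, or 0.988 with an estimated correlation). Ribosome assembly was not tested as a set, and other families with such factors were not called: RRP (5 of 9 higher, 1 lower, adjusted p = 0.153), NOL (4 of 9 higher, 1 lower, 0.489) and EXOSC (5 of 10 higher, 0 lower, 0.617).

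The DUSP family of dual-specificity phosphatases, several of which switch off MAP kinases, had 10 of 15 tested genes higher and 2 lower (adjusted p = 2.06e-05, or 0.588 with an estimated correlation). DUSP10 rose from 1.12 to 6.72 FPKM (log2 fold change 2.54, SE 0.16) and DUSP8 from 0.540 to 2.88 FPKM (2.39, SE 0.14). The DNAJB and HSPA prefixes had 7 of 10 and 7 of 11 tested members higher and 0 lower (adjusted p = 0.00773 for both, or 0.988 with an estimated correlation). Each includes a pseudogene, DNAJB6P1 (0.49, adjusted p = 0.0249), which is among the 7 that rose, and HSPA8P15 (-0.79, adjusted p = 0.0597). Among families that fell, ALDH, the aldehyde dehydrogenases, had 9 of 12 lower and 1 higher (adjusted p = 0.0393, or 0.988 with an estimated correlation), with ALDH3B1 at -0.84 (SE 0.11). MCM had 5 of 10 lower and 0 higher (adjusted p = 0.00773), and PRR had 6 of 11 lower and 0 higher (0.0393). Both had adjusted p = 0.988 with an estimated correlation. The 5 lower MCM genes, MCM2 to MCM6, are also in the DNA replication and G1/S list. DUSP1 is also among the immediate early genes, and HSPA8 and DNAJB1 are among the heat shock genes. These families thus partly repeat the results of those lists. The MT family repeats the metallothioneins, with 9 of 9 higher (adjusted p = 3.82e-43, or 0.588 with an estimated correlation). With an estimated correlation every family had a camera adjusted p of at least 0.588. This held even for MT, whose median log2 fold change was 7.13, so these values decide nothing for or against a family.

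The metallothionein transcripts were higher in all 3 treated libraries. Summed over all 18 metallothionein genes and pseudogenes, counts rose from 79 to 86 per control library to 6915 to 12305 per treated library, a log2 fold change of 6.64 (SE 0.20), which argues against reads only moving between near-identical copies. A response to metal is a candidate explanation, since the zinc exporter SLC30A1 rose by 1.44 (SE 0.12) and the zinc importer SLC39A10 fell by 2.05 (SE 0.13) on the log2 scale, but these values had been seen before the test was chosen. Glucocorticoid receptor activity, which also induces metallothioneins, stays open: its 9 other tested targets had a median of -0.078 (SE 0.32), with 4 higher and 4 lower, and members that go both ways decide nothing. Whether metal entered with the compound or the medium was not tested.

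Of the tested replication-dependent histone transcripts 9 of 10 were higher, while 22 of 32 tested genes of DNA replication and G1/S were lower, 1 was higher and 9 did not pass. Counts summed over 66 histone genes of the clusters gave a log2 fold change of 1.71 (SE 0.048), which argues against reads moving between copies. More cells in S phase would raise the genes of the DNA replication and G1/S list. The list's median was -0.28, which argues against it, although the share of cells in S phase was not measured. That list's call did not hold with an estimated correlation (adjusted p = 0.166). A higher share of RNA without poly(A) tails in the treated libraries would raise other such RNAs, but the 4 tested (RN7SL1, SNORA73B and the mitochondrial MT-RNR1 and MT-RNR2, which carry short tails) had a median of -0.034 (SE 0.12), against 2.21 for the histones. The 2 nuclear ones had a median of -0.076 (SE 0.22), and 14 small nuclear, nucleolar and similar RNAs with at least 60 counts had a median of -0.44 (SE 0.23). Histone RNA with poly(A) tails was not told apart from histone RNA without them, so a rise of the tailed forms stays open.

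TXNIP, ARRDC4 and PKLR, known targets of the glucose-sensing factors ChREBP and MondoA, were lower, with ARRDC4 at -2.35 (SE 0.19) chosen after its value was seen. Offsets for GC content and gene length left the median of the 3 genes at -2.55, against -2.53 without them, and moved the tested genes by an SD of 0.062, which argues against such a trend as the whole cause. Lower activity of these factors is a candidate explanation: of 12 other ChREBP targets, 9 were tested, 8 fell and 1 rose, with a median of -0.39 (camera p = 0.000911, or 0.112 with an estimated correlation). That test is weak, since 5 of the 9 sit in lists already known to contain falling genes, and the other 4 (3 fell and 1 rose) had a median of -0.39 with an SE of 0.47. A general fall of lipid synthesis and liver genes would move the same targets and was not told apart from it.

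The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large cannot be under 0.05 here. For the 6486 changed genes the highest count in another split was 0, and 1 of the 10 splits (the real one) reached the real count. At an absolute log2 fold change of at least 1 the real count was 497 and the highest other count 0, again with 1 of 10 splits as large. For the lists, 4 of 10 splits called at least the 9 lists called higher (highest other 11), and 3 of 10 at least the 8 called lower (highest other 10). Each of those other splits sets 2 treated libraries and 1 control against 1 treated library and 2 controls, so it keeps part of the treatment difference. Camera compares a list's genes with the other genes of the same split. These list counts are therefore no reference without an effect and decide nothing about the real counts. Each of the 9 called 0 genes with edgeR, with 52 to 126 genes at an unadjusted p under 0.05, against 7233 in the real split. Each puts treated and control libraries in the same group, which adds the treatment difference to the spread within groups. A count of 0 was thus largely set by the design, and these gene counts are no reference without an effect either.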
